A study of Mus musculus with 12 samples.

How the data were processed

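Total RNA was extracted with Trizol from the hippocampus and olfactory bulb of adult C57BL/6 mice, fragmented and labelled with biotin, and hybridised to 1-colour arrays, 1 per sample, per the labels' protocols. The 12 samples are 3 wild-type and 3 RasGRF2 knockout animals with 2 tissues each. Each sample's genotype, tissue and animal number come from its title. The animals also carry a code (I547, N135 and N138 in wild type, N384, N386 and N390 in knockout), and for a pair of wild-type animals the code and the title's number pair the tissues differently. The code was used where tissues of an animal were joined, and the title's number was run as an alternative.

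The authors deposited 1 log2 value per probe set and sample. Per the submitters' processing notes these values were made with RMA and the oligo package. RMA corrects background, applies quantile normalization between arrays and summarises probes to a log2 intensity, so it forces arrays normalized together to a common distribution and compresses differences near background. Tool versions and whether the tissues were normalized together are not given in the sources used here. The array medians differ between the tissues and vary within each, so the distributions were not identical over the probe sets deposited. No genome build is given in the sources used here, so no coordinates are printed.

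The deposited values cover 35556 probe sets. The platform's annotation lists 23410, of which 21789 have 1 gene symbol and 1621 several; 12146 are not listed and are unnamed here. Of the single-symbol probe sets, 21698 were matched by Entrez identifier to a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. This gene list was used for names and for the order of neighbouring genes. Where a gene had more than 1 probe set (999 genes), the probe set with the highest mean over the 12 arrays stood for it, which left 19938 genes. No gene was filtered out for low signal. Arrays carry no read depth, and their number limits the precision. Replicate pairs within a group differed across probe sets with an SD of 0.212 to 0.297 on the log2 scale, so no array was a copy of another.

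Group differences were tested with limma 3.58.1 in R 4.3.3, on the log2 values as deposited, with lmFit and eBayes at default settings and Benjamini-Hochberg adjustment over the genes at 0.05. A single model of the 4 group means over all 12 arrays gave knockout against wild type in each tissue, the difference of these effects, and hippocampus against olfactory bulb in each genotype. For the comparison averaged over tissues, the tissues of each animal were averaged first, so that 3 animals were set against 3. Fold changes are differences of mean log2 values, with limma's standard errors. The limma p-values of single genes rest on the spread between arrays of a group, which come from different animals. Comparisons between the tissues leave out their pairing except where the animal is a block. The tests of lists by camera and of neighbouring genes set genes against other genes. Values were read with the data.table package (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

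Lists of cell type markers and pathway genes, 31 in all, the rule for the genes named, the tests of the comparisons and the other settings tried were fixed before the data were examined. Several tests of the closing section were chosen later and are named there. Older and newer symbols of a gene were matched through the gene table, and 387 of 422 list entries were measured. The 30 lists with at least 3 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. The list of blood genes was too short to test. Members were counted over all genes and adjusted over the list alone. At the preset correlation camera treats the genes of a list as nearly independent, which markers of a cell type are not.

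The rule for the genes named in the text takes Rasgrf2 first, then, in each comparison of genotypes, the 10 largest changes in each direction among genes past the threshold. Where fewer than 10 passed in a direction it adds the 5 genes of smallest p that did not pass. In each comparison of tissues it takes the 10 largest changes in each direction. It adds every gene past the threshold in both tissues, 12 markers of the neurogenic sequence and from each list the members past the threshold, at most 6, with up to 3 others as examples. Genes with clone, predicted-gene, small RNA or chemoreceptor names count but are not named, and genes named outside the rule are marked as such.

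The pipeline was tested on simulated data in which 200 of 19938 genes were changed, over 20 simulations for each comparison. Normal noise with limma's moderated spread of each gene was added to its mean in each tissue. For comparisons between the tissues it was added to the mean over all arrays. For knockout hippocampus it recovered 89.8% of changes of 0.5 log2 and 99.9% of changes of 1, with 5.44% false calls. For the difference of effects between tissues it recovered 47.2% of changes of 0.5 and 98.9% of changes of 1. When 30 lists were shifted in turn by 0.3 log2 in simulated hippocampus, each of the 30 was found. Lists that shared no gene with the shifted one were called 5 times over all runs. The simulated genes varied independently of each other, so these runs cannot show how the set test behaves on lists of correlated genes. They also held no outlying array and no level shared by an animal, so they do not show recovery or false calls under these.

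The other settings were a fit of only the groups compared, eBayes with trend and robust settings, every probe set in place of 1 per gene, only genes above the median level, median centring of each array, a further quantile normalization, array weights, each replicate left out in turn, the animal as a block, and other ways of joining tissues. Whether the animal labels pair the tissues was checked by correlating deviations from the group means between tissues of an animal. By the code these correlations ran from -0.255 to 0.116, and by the title's number, for the animals where the labels differ, from -0.153 to 0.252. Arrays of different animals gave -0.325 to 0.359. The estimated correlation within an animal was -0.0697. Tissues of an animal are paired by design, and the block is therefore reported where it changed a call. Chromosome neighbourhood was tested by Fisher's exact test and by random draws of genes.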

Results

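Gene expression was measured in adult mice that lacked RasGRF2 and in wild-type mice, both labelled C57BL/6. Whether they were littermates, and how far the mutation had been backcrossed, is not given in the sources used here. RasGRF2 is an exchange factor that loads GTP onto Ras and Rac proteins and is expressed in neurons. Hippocampus and olfactory bulb, brain regions that hold or receive adult-born neurons, were taken from 3 wild-type and 3 knockout animals. The 12 samples of total RNA, each hybridised to its own 1-colour array, form 4 groups of 3, and every group of a tissue holds separate animals. The deposited values are log2 intensities after robust multi-array averaging (RMA), for 35556 probe sets, of which 21789 carry 1 gene symbol and stand for 19938 genes. Values ran from 2.94 to 14.37, and array medians lay between 6.93 and 6.96 in olfactory bulb and between 6.82 and 6.89 in hippocampus. Tissue was the main axis of variation, since the first principal component held 79.6% of the variance and parted the tissues. Within a tissue, arrays correlated across probe sets with r of at least 0.989 in olfactory bulb and 0.984 in hippocampus. The lowest values in hippocampus came from knockout replicate 6, which also lay farthest out on the second component, at -19.5. In all 12 arrays the Y-linked genes Kdm5d, Eif2s3y and Uty lay at 7.40 or above, and Xist, transcribed from the inactive X of females, at 4.61 or below. The 3 arrays per group limit the precision of every value below.

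The targeted gene was examined first. In the hippocampus Rasgrf2 was at 8.63 ± 0.13 (SD, n = 3) on the log2 scale in knockout and at 9.21 ± 0.091 in wild-type arrays, a difference of -0.58 (SE 0.077, limma adjusted p = 0.00197). All 3 knockout values, 8.64, 8.76 and 8.49, lay under the wild-type values of 9.32, 9.14 and 9.18. In the olfactory bulb the knockout arrays read 9.33, 9.35 and 9.43 against 9.52, 9.52 and 9.47, a difference of -0.14 (SE 0.077) that did not pass the test (adjusted p = 0.532). The gene is represented by a single probe set, and which exons were deleted is not given in the sources used here. The 3 knockout values of the bulb also lay under its 3 wild-type values. A probe outside the deleted part would not report the deletion itself. The difference between the tissues in the Rasgrf2 effect was -0.45 (SE 0.109) and did not pass either (adjusted p = 0.33).

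**Figure D1:**
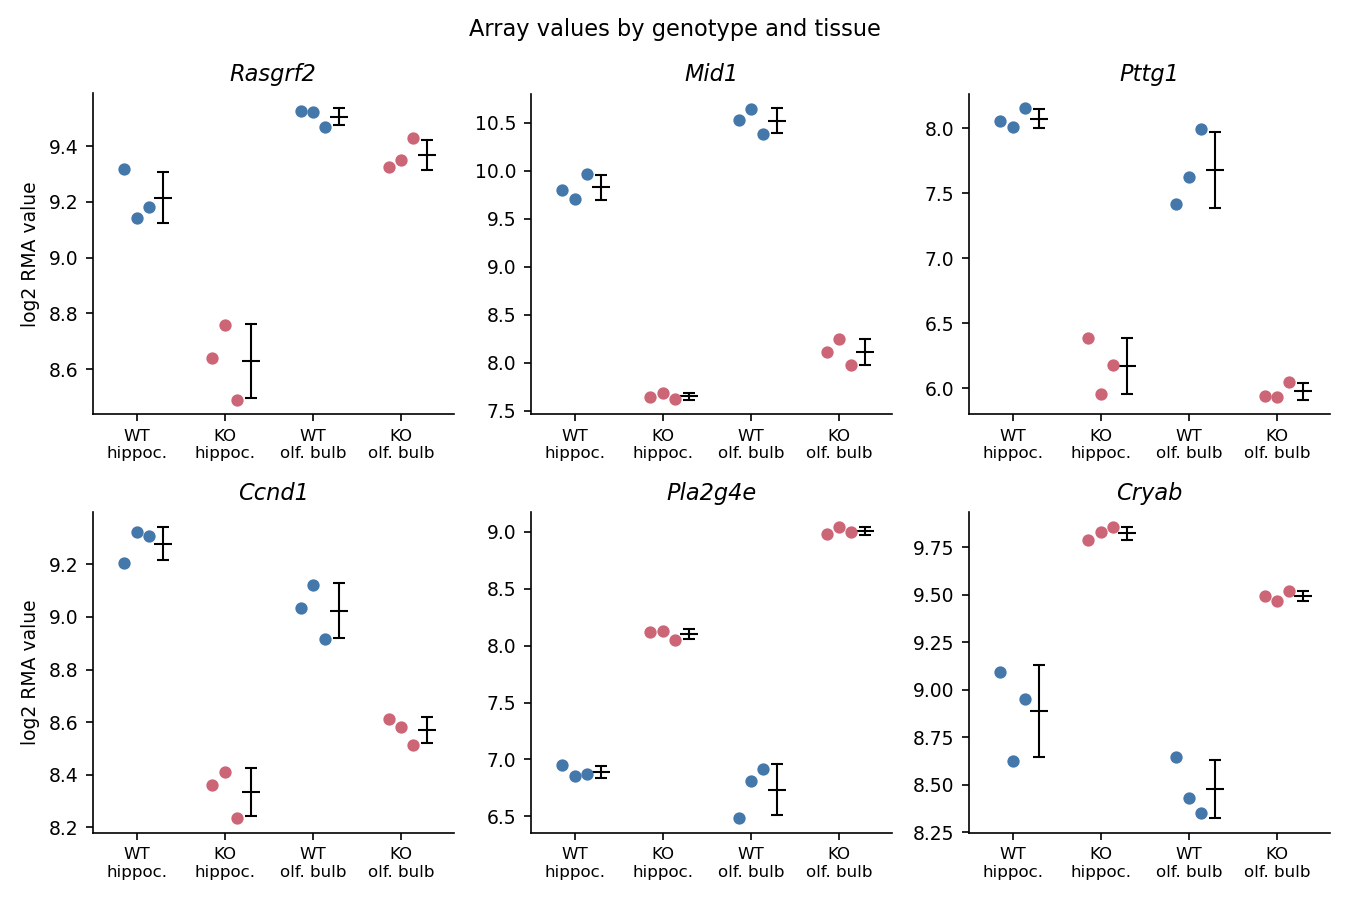
Log2 RMA values of 6 genes in each of the 12 arrays (points, blue for wild type and red for knockout), with the mean and SD of each group of 3 (black). Mid1, Pttg1 and Ccnd1 lie lower, and Pla2g4e and Cryab higher, in every knockout array than in every wild-type array of the same tissue; Rasgrf2 differs by -0.58 in hippocampus and by -0.14, short of the threshold, in olfactory bulb.

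The comparison of knockout with wild-type hippocampus asks which transcripts differ in the region whose stem cells and young neurons the study examined. Among genes with a single symbol, the largest decrease was that of Mid1, a microtubule-associated ubiquitin ligase, which fell by 2.17 on the log2 scale, or 4.51-fold (SE 0.090, adjusted p = 7.26e-09). Pttg1, the securin that holds back sister chromatid separation, fell by 1.90 (SE 0.127, adjusted p = 2.95e-06), and Ccnd1, the cyclin D1 of G1 phase, fell by 0.94 (SE 0.075, adjusted p = 1.41e-05). Sv2c, a glycoprotein of synaptic vesicles, changed by -1.11 and Iyd, an iodotyrosine deiodinase, by -0.99. Among the increases, Pla2g4e, a cytosolic phospholipase A2, rose by 1.21 (SE 0.091, adjusted p = 1.02e-05), or 2.31-fold. Serpina3n, a protease inhibitor known from reactive astrocytes, rose by 0.97 and the small heat shock protein gene Cryab by 0.94. The haem-binding protein gene Hebp1 (0.90), the hyaluronan receptor gene Layn (0.88), the zinc transporter gene Slc39a2 (0.80), the cohesin acetyltransferase gene Esco1 (0.69), the kinase gene Hunk (0.67), Slc35f4 (0.66) and the serotonin receptor subunit gene Htr3a (0.65) were also higher in knockout. Mcmdc2 (-0.90), Ccnb1ip1 (-0.88) and Ddx4 (-0.76), genes known from germ cells, were lower in knockout, at mean values of 5.33, 5.20 and 5.44 there, below the array medians. The amino acid transporter gene Slc38a6 (-0.72) and Nfu1 (-0.71), which serves iron-sulfur cluster assembly, were lower too. B2m, the light chain of class I MHC molecules, changed by -0.60 (adjusted p = 0.0371, past the threshold in 7 of 13 alternatives).

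In all, 51 of 19938 genes passed a limma adjusted p of 0.05 in hippocampus, 29 higher and 22 lower in knockout, and 4 of them changed more than 2-fold. At an unadjusted p under 0.05 there were 1776 genes, where chance would give 996.9. The count was 28 when only the hippocampal arrays were fitted, 125 over every probe set (49 higher and 76 lower), 336 with array weights and 20 higher against 25 lower after each array was centred on its median. It was 42 without knockout replicate 6, 30 without wild-type replicate 1, 32 without knockout replicate 5 and 33 without wild-type replicate 3.

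The markers of the neurogenic sequence fixed beforehand did not pass the test in hippocampus. The arrays read whole tissue, so a change confined to few cells may fall short of the test. Nes, the stem cell filament nestin, differed by 0.17 (SE 0.122, adjusted p = 0.704) at values of 5.71 ± 0.041 in knockout and 5.55 ± 0.26 in wild type (SD, n = 3). Both Nes means lay below the array medians. Among the other stem cell and progenitor markers, Sox2 differed by 0.02, Gfap by -0.09, Mki67 by 0.20 and Eomes by -0.06. Among neuronal markers, Dcx, made in migrating young neurons, differed by -0.14 (SE 0.063, adjusted p = 0.559), Neurod1 by -0.14, Calb2 by -0.22, Prox1 by -0.12, Calb1 by -0.04 and Rbfox3 by -0.04. Of the list of 18 neural stem cell and radial glia genes, none passed over all genes and 2 passed adjusted over the list alone, Id4 (-0.24) and Vim (-0.40). The list lay lower as a set (camera adjusted p = 0.0184), which did not hold with an estimated correlation (adjusted p = 0.643). Its mean in the knockout arrays lay 0.075, 0.014 and 0.071 log2 under the wild-type mean, and the wild-type arrays themselves spanned -0.044 to 0.062. None of 19 progenitor cell cycle genes passed (13 higher, 6 lower, camera adjusted p = 0.679), nor did any of 18 immature neuron genes (camera adjusted p = 0.493, direction down, with a median of 0.021).

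Other marker lists shifted by small amounts in hippocampus. All 13 myelin genes lay higher in knockout, with a median of 0.24 (camera adjusted p = 0.000457, adjusted p = 0.66 with an estimated correlation) and none past the threshold alone, for example Mobp (0.30), Trf (0.30) and Mog (0.35). Their mean stood at 0.0051, 0.29 and 0.33 over the wild-type mean in knockout replicates 4, 5 and 6. All 10 ependymal and cilia genes lay higher, with a median of 0.18 (adjusted p = 0.00796, adjusted p = 0.643 with an estimated correlation), Rsph1 by 0.33 and Tmem212 by 0.23. Of 14 dentate granule neuron genes 12 lay lower (median -0.13, adjusted p = 0.00101, adjusted p = 0.66 with an estimated correlation), among them Plk5 (-0.25) and Dock10 (-0.17). Knockout replicate 6 carried most of that difference, with a mean of -0.28 against 0.014 and -0.059 in the other knockout arrays. Of 13 meningeal and fibroblast genes 10 lay lower (median -0.30, adjusted p = 0.000896, adjusted p = 0.66 with an estimated correlation), with Lum at -0.65 past the threshold over the list alone. The wild-type arrays of this list ranged from -0.45 to 0.48 around their mean. Of 19 immediate early genes 16 lay lower, with a median of -0.07 (adjusted p = 0.000896, adjusted p = 0.66 with an estimated correlation) and Btg2 (-0.58) past the threshold over the list alone. Of the 24 lists that did not pass, adjusted p ran from 0.0538 to 0.869. They include the Ras pathway without Rasgrf2 (0 of 20 genes past the threshold) and the ERK feedback genes, where Ccnd1 alone of 15 passed. The ERK feedback list had a median of 0.066 and a mean of -0.010.

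**Figure D2:**
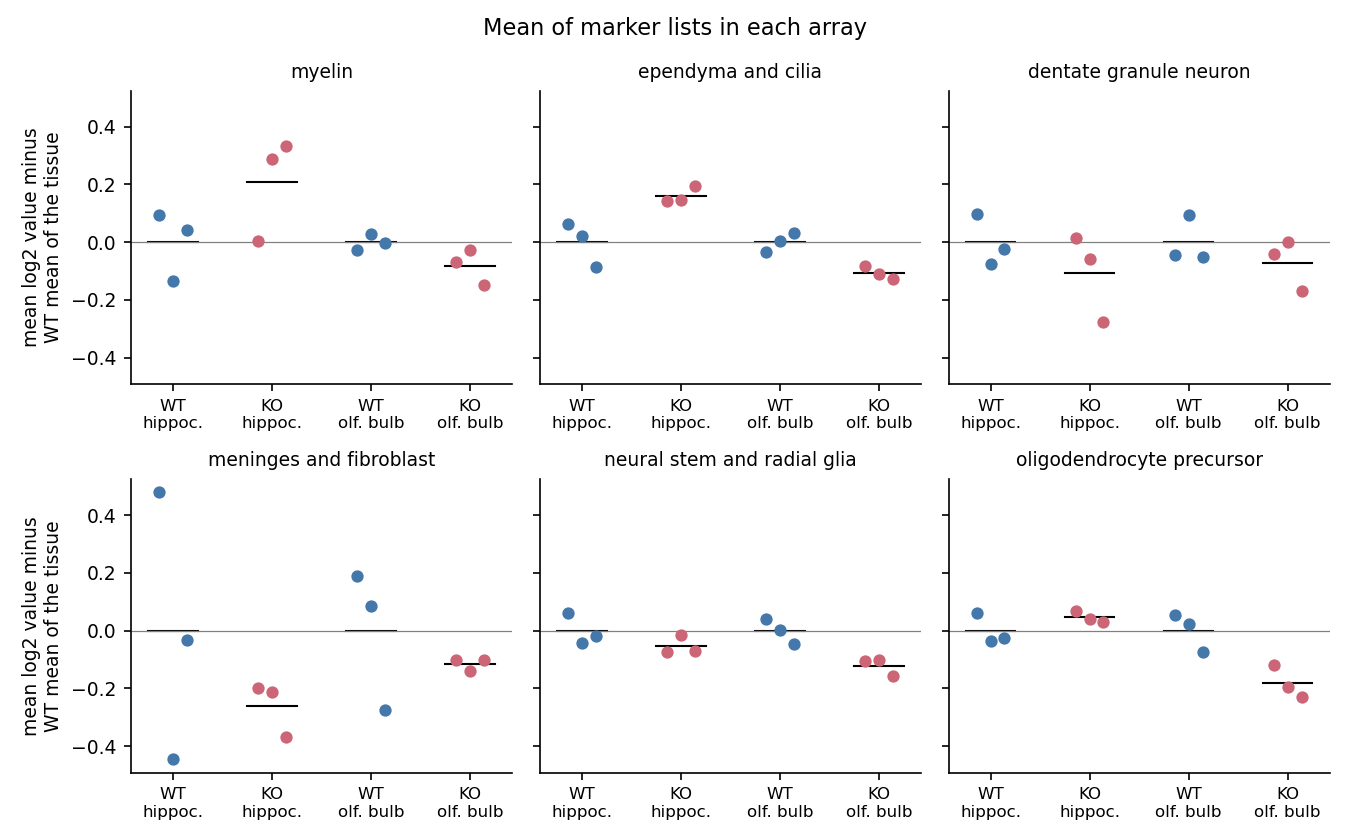
Mean log2 value of 6 marker lists in each array (points, blue for wild type and red for knockout), minus the mean of the wild-type arrays of the same tissue, with the group mean as a black line. The 3 knockout hippocampal arrays stand at 0.0051, 0.29 and 0.33 for myelin genes and the wild-type hippocampal arrays at -0.45 to 0.48 for meningeal and fibroblast genes.

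In the olfactory bulb Mid1, Pttg1 and Pla2g4e again led the differences between knockout and wild type among genes with a single symbol. Mid1 fell by 2.41 (SE 0.090, adjusted p = 1.67e-09), or 5.31-fold, and Pttg1 by 1.70 (SE 0.127, adjusted p = 8.88e-06), while Pla2g4e rose by 2.27 (SE 0.091, adjusted p = 2.24e-09), or 4.84-fold. Tnfaip6, a secreted hyaluronan-binding protein, fell by 1.33 (adjusted p = 7.99e-05) and Slc38a6 by 1.04. Cryab rose by 1.02, Esco1 by 1.00, Greb1l by 0.98, the nicotinic receptor subunit gene Chrna3 by 0.97, Htr3a by 0.90 and Slc39a2 by 0.90. Dlx5, a homeobox factor of forebrain interneurons, rose by 0.84 (adjusted p = 0.00117), Etnppl, a phospho-lyase of phosphoethanolamine, by 0.68 (past the threshold in 4 of 12 alternatives) and the protocadherin gene Pcdhb2 by 0.63. Mcmdc2 (-0.81), Adhfe1 (-0.75), a mitochondrial transhydrogenase gene, and Klhl33 (-0.65) were lower. Ccnd1 fell by 0.45 (SE 0.075, adjusted p = 0.0133).

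Immediate early genes, which neurons transcribe within minutes of activity, lay lower in the knockout olfactory bulb. All 19 measured members had negative differences, with a median of -0.34 (camera adjusted p = 8.87e-11, adjusted p = 0.601 with an estimated correlation), and 6 fell past the threshold over all genes, 9 adjusted over the list alone. The transcription factor genes Fosb fell by 1.07 (SE 0.209, adjusted p = 0.0415) and Npas4 by 0.98 (SE 0.198, adjusted p = 0.0468), the antiproliferative gene Btg2 by 0.75 (SE 0.128, adjusted p = 0.0188), Egr3 by 0.50, Egr4 by 0.49 and Nr4a2 by 0.47. Under 13 alternatives the adjusted p of Fosb ran from 0.0218 to 0.194 and passed in 5, and that of Npas4 from 0.0206 to 0.232 and passed in 5. Btg2 passed in 7, Egr3 and Egr4 in 6 each and Nr4a2 in 4 of the 13. The median of the list was -0.19 without wild-type replicate 3, the array with the highest level of the list at 9.31. Fry, which tests whether the genes move one way on balance, gave an adjusted p of 0.192. Of 15 ERK feedback genes, Dusp4, a phosphatase gene that ERK signalling induces, fell by 0.49 (adjusted p = 0.0294, past the threshold in 5 of 12 alternatives) and Ccnd1 fell, while 10 of the 15 lay above 0 (camera adjusted p = 0.628, median 0.037, mean -0.0046).

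**Figure D3:**
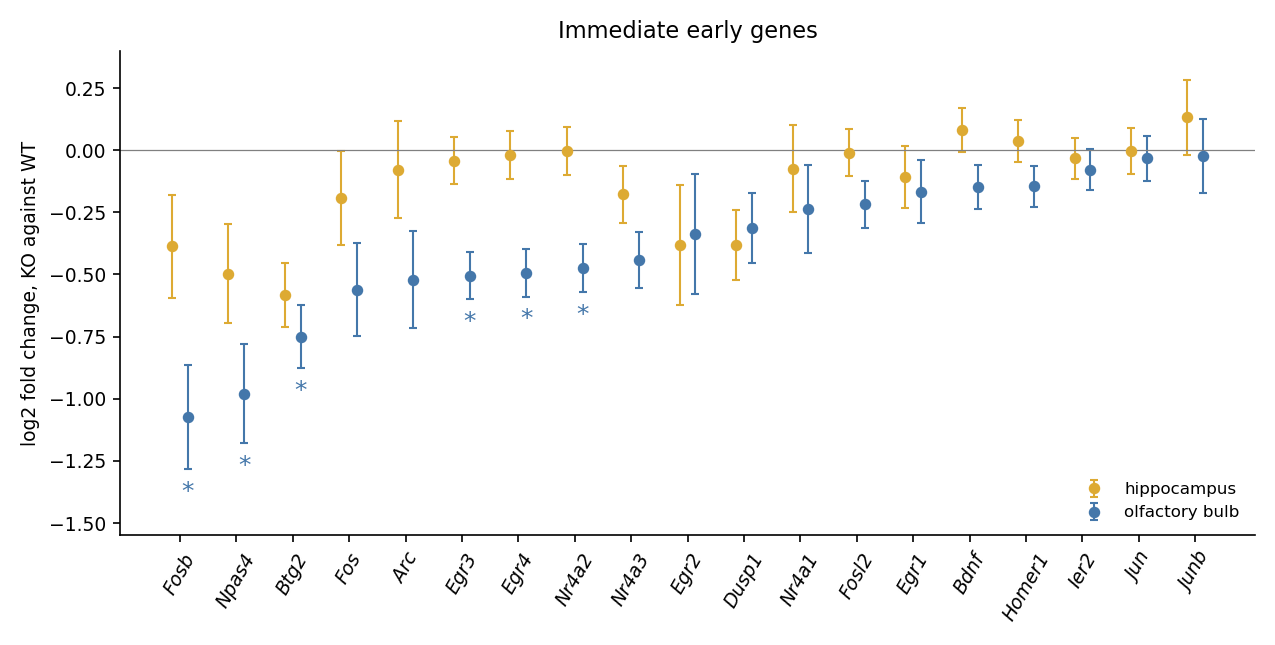
Log2 fold change, knockout against wild type, of 19 immediate early genes in hippocampus (yellow) and olfactory bulb (blue); points are limma estimates from 3 against 3 arrays and bars are standard errors. Asterisks mark the 6 genes with an adjusted p under 0.05 over all genes, all in olfactory bulb; the median is -0.34 in olfactory bulb and -0.07 in hippocampus.

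Markers of the neurogenic sequence did not pass in the olfactory bulb either, with the same limit of whole tissue. Nes differed by -0.31 (SE 0.122, adjusted p = 0.386), Gfap by -0.33, Sox2 by 0.16, Mki67 by -0.04, Dcx by 0.06, Neurod1 by -0.13, Calb2 by 0.17, Calb1 by 0.05, Prox1 by -0.06 and Rbfox3 by -0.09. Eomes, made in mitral and tufted cells of the bulb, differed by 0.36 (adjusted p = 0.242). Among 18 neural stem cell and radial glia genes Id4, an inhibitor of helix-loop-helix factors, fell by 0.34 (adjusted p = 0.0375, past the threshold in 5 of 13 alternatives), and Hopx (-0.32) and Vim (-0.46) joined it when adjusted over the list alone, a count of 3. The list lay lower as a set (camera adjusted p = 0.0342, adjusted p = 0.601 with an estimated correlation). Of 9 oligodendrocyte precursor genes 8 lay lower (median -0.19, camera adjusted p = 0.00821, adjusted p = 0.435 with an estimated correlation), with Pdgfra (-0.25), Olig2 (-0.25) and Bmp4 (-0.48) past the threshold over the list alone. Of the 3 lists called in the bulb, 1 passed without wild-type replicate 1, and 5 lists passed without wild-type replicate 3. Wild-type replicate 1 also carried, as seen only after the values were examined, the highest values of Cyp2g1, an enzyme gene of the nasal mucosa, at 8.29 against 5.37 to 5.68 in the other olfactory bulb arrays, and of Stoml3, a gene of olfactory sensory neurons, at 10.07 against 7.87 to 9.24. Of the same list of olfactory sensory and epithelium genes, Cnga2 and Gnal were also highest there. Omp, S100a5, Gng13, Adcy3 and Ano2 were not. Of the 27 lists that did not pass, adjusted p ran from 0.069 to 0.95, the olfactory bulb neuron list among them (10 of 14 genes higher).

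In total 82 genes passed in the olfactory bulb, 37 higher and 45 lower in knockout, and 7 changed more than 2-fold. At an unadjusted p under 0.05 there were 2245. Over every probe set 80 were higher and 24 lower, with 41 of the 82 genes among them. Of these probe sets, 54 of the higher and 5 of the lower had no single gene symbol. Fitting only the bulb arrays gave 36 genes and moderation with trend and robust settings gave 136. Leaving out knockout replicates 4, 5 and 6 in turn gave 41, 50 and 35 genes, and leaving out wild-type replicates 1 and 2 gave 38 and 40.

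The tissues were then set against each other, to see which differences between knockout and wild type they shared. Of the genes past the threshold, 24 passed in both tissues, 11 of them higher in both and 12 lower in both, where independent lists of these sizes would share 0.0538 and 0.0497. The shared decreases were Mid1, Pttg1, Ccnd1, Mcmdc2, Ccnb1ip1, Ddx4, Slc38a6, Nfu1, Adhfe1, the augmin subunit gene Haus2, the leucine catabolism gene Ivd and Snapc1, whose product serves small nuclear RNA transcription. The shared increases with a gene name of the kind reported here were Pla2g4e, Cryab, Esco1, Htr3a, Slc39a2, Greb1l, Pcdhb2, Nxpe4 and the kinase gene Riok3. Armh4 passed in both tissues with opposite directions. Mid1, Pttg1, Mcmdc2, Slc38a6, Ivd, Snapc1, Pla2g4e, Cryab, Htr3a and Slc39a2 passed in both tissues under every alternative run for them. The shared calls of others were often lost in a tissue. In olfactory bulb Ddx4 and Nxpe4 each passed in 4 of 12 alternatives, Ccnb1ip1 in 5 of 12, Nfu1 and Armh4 in 6 of 13 and Ccnd1 in 8 of 13. In hippocampus Greb1l passed in 5 of 12, Nxpe4 in 8 of 12, Adhfe1 in 6 of 13, Riok3 in 7 of 13 and Pcdhb2 and Armh4 in 9 of 13. Hippocampal and bulb arrays came from the same 6 animals, so the lists are not independent of the animals. Most of the genes past the threshold in both tissues also lay in runs of called neighbours along a chromosome. Of the genes that passed under every alternative, all but Mid1 and Pttg1 lay in such runs. Lying outside a run does not exclude a strain difference at a single gene, and this was not tested for Mid1 or Pttg1. The cause of the runs stays open in the closing section. Across the 51 genes called in hippocampus, log2 fold changes in the tissues correlated with r = 0.831, and 45 had the same sign in olfactory bulb; genes are not independent replicates. Across all 19938 genes r was 0.0788, Spearman's rho was -0.0586 and 9276 genes had the same sign.

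**Figure D4:**
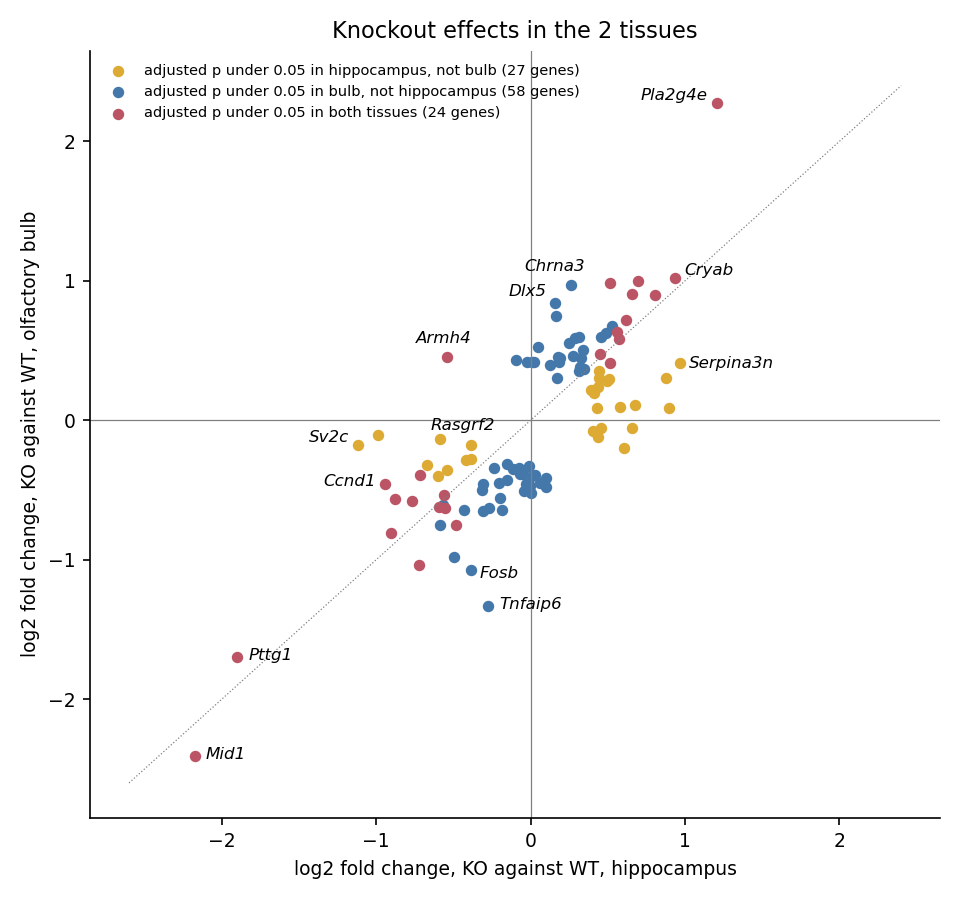
Log2 fold change, knockout against wild type, in hippocampus (horizontal) and olfactory bulb (vertical) for each gene with a limma adjusted p under 0.05 in hippocampus and not in bulb (27, yellow), in bulb and not in hippocampus (58, blue) or in both (24, red). The dotted line marks equal change; Mid1, Pttg1 and Pla2g4e stand farthest from 0 in both tissues, and Armh4 has opposite signs.

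The interaction test called 3 genes whose knockout effect differed between the tissues. Pla2g4e rose less in hippocampus than in olfactory bulb, with a difference of effects of -1.06 (SE 0.129, adjusted p = 0.00875). Armh4 fell by 0.54 in hippocampus and rose by 0.45 in olfactory bulb, a difference of -0.997 (SE 0.123, adjusted p = 0.00875). Sv2c changed by -1.11 in hippocampus and by -0.18 in olfactory bulb, a difference of -0.94 (SE 0.134, adjusted p = 0.0318). Sv2c lies on the chromosome of Rasgrf2, within 40 Mb of it, and may be the 1 hippocampal call within 5 Mb. Sequence carried along with the mutation is therefore not excluded for it. The genes of smallest p that did not pass were Tnfaip6 with 1.06 (adjusted p = 0.124), Slc35f4 with 0.72, Erich5 with 0.80, Rnf186 with 0.67, Ptpn18 with 0.63 and Iyd with -0.88 (adjusted p = 0.136 for each of the last 5). Cybrd1 (-0.48), Samsn1 (-0.52), Ccnd1 (-0.49, adjusted p = 0.228) and Dlx5 (-0.68) followed. Of the marker genes, Nes differed by 0.47 (adjusted p = 0.392) and Dcx by -0.19 (adjusted p = 0.467) between the tissues. An unadjusted p under 0.05 was reached by 2124 genes, where chance would give 996.9. With the animal as a fixed block the count was 0, by code or by title number, and as a random block by code it was 3, the same genes. The count was 0 over every probe set, 12 with array weights, and 0 without knockout replicate 4 of either tissue.

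By camera at the preset correlation, 4 lists had a different knockout effect in the tissues, and none did with an estimated correlation. The 13 myelin genes (median difference 0.31, camera adjusted p = 0.00189, adjusted p = 0.853 with an estimated correlation) and the 10 ependymal and cilia genes (0.31, adjusted p = 0.00343, adjusted p = 0.371 with an estimated correlation) lay higher in knockout hippocampus relative to bulb, every member with a positive difference. The same held for the 9 oligodendrocyte precursor genes (0.23, adjusted p = 0.0161, adjusted p = 0.371 with an estimated correlation) and for 17 of the 19 immediate early genes (0.21, adjusted p = 0.0146, adjusted p = 0.926 with an estimated correlation). Fry gave an adjusted p of 0.0323 for both the ependymal and the precursor list, 0.449 for myelin and 0.75 for immediate early genes.

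With each animal represented by the mean of its tissues, 115 genes passed between 3 knockout and 3 wild-type animals, 62 higher and 53 lower. Rasgrf2 was lower by this measure, at -0.36 (SE 0.053, adjusted p = 0.00822, past the threshold in 11 of 14 alternatives). Mid1 changed by -2.29, Pttg1 by -1.80, Ccnd1 by -0.70, Tnfaip6 by -0.80, Slc38a6 by -0.88, Mcmdc2 by -0.86, Ccnb1ip1 by -0.72 and Ddx4 by -0.67. Srsy (-0.91), a Y-linked gene, and Bub1b (-0.71), a spindle checkpoint kinase gene, passed here and in neither tissue alone. Bub1b passed in 6 of 13 alternatives, with adjusted p from 0.00266 to 0.175, and its bulb value in wild-type replicate 3 was 7.22 against 6.12 and 6.15. Srsy and Etnppl each passed in 10 of 13. Pla2g4e changed by 1.74, Cryab by 0.98, Esco1 by 0.85, Slc39a2 by 0.85, Htr3a by 0.78, Greb1l by 0.75, Serpina3n by 0.69, Chrna3 by 0.61, Etnppl by 0.60 and Pcdhb2 by 0.60. None of the measured markers of the neurogenic sequence passed, Nes at -0.07 (adjusted p = 0.819) and Dcx at -0.04 (adjusted p = 0.841). After median centring the split was 52 higher and 72 lower, over every probe set 77 and 29, trend and robust settings gave 181 genes, and leaving out the knockout animal N384 or the wild-type animal N135 left 69 genes. Of the 115 genes, 39 still passed over every probe set.

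The regions themselves differed far more than the genotypes. In wild type 8148 genes passed between hippocampus and olfactory bulb, 3480 higher in hippocampus and 4668 higher in bulb, and 953 differed more than 2-fold. With the animal as a block the count was 7478 by code and 7718 by title number. Highest in hippocampus relative to bulb were Neurod6 (4.20), a transcription factor of pyramidal neurons, Prdm8 (4.08), Cabp7 (3.99), Iqgap2 (3.80), Prox1 (3.31), the factor of dentate granule neurons, Crym (3.24), Npy2r (3.22), Itpka (3.12), Cdh9 (3.00) and Grp (2.95). Highest in bulb were Cpa6 (-4.81), Lgr5 (-4.77), Th (-4.65), the tyrosine hydroxylase of dopaminergic periglomerular cells, Pbx3 (-4.60), Frmd7 (-4.54), Vipr2 (-4.29), Abi3bp (-4.10), Eomes (-4.08), Gng4 (-4.08) and Cdhr1 (-3.98). All 14 genes of the olfactory bulb neuron list were lower in hippocampus, with a median of -2.93 (camera adjusted p = 3.53e-17, adjusted p = 0.00186 with an estimated correlation). Of 13 CA pyramidal neuron genes 11 were higher in hippocampus (adjusted p = 1.81e-07, adjusted p = 0.11 with an estimated correlation), as were 10 of 14 dentate granule neuron genes (adjusted p = 4.82e-05, adjusted p = 0.435 with an estimated correlation). The other 4 dentate granule genes and 1 of the pyramidal genes passed in the opposite direction, higher in bulb.

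In knockout animals 7804 genes passed between the regions, 3838 higher in hippocampus and 3966 higher in bulb; with the animal as a block the count was 7224 by code. The leading genes were Iqgap2 (4.24), Cabp7 (4.19), Neurod6 (3.88), Prdm8 (3.83) and Crym (3.66) on the hippocampal side and Lgr5 (-4.61), Cpa6 (-4.59), Frmd7 (-4.53), Eomes (-4.51) and Th (-4.47) on the bulb side. Enc1 (3.22), a kelch-repeat protein gene, was among the 10 highest in hippocampus in knockout and not in wild type. This is a difference of rank only, as Enc1 was not among the 3 genes called by the interaction test. Across genes the regional fold changes of the genotypes correlated with r = 0.935, and 2855 genes were higher in hippocampus and 3249 higher in bulb in both. The split of calls depended on scaling. After median centring 4417 were higher in hippocampus and 3274 in bulb in wild type, and 4331 and 3626 in knockout; quantile normalization over all arrays gave 4131 and 3758 in wild type, and 5096 and 3523 in knockout.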

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

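The tests of a state of the whole animal and of single libraries below were chosen only after the result was seen, and that of time of day was set before it. The criterion for the whole-animal test was also tightened after its value was known, by asking for the smallest exact p in addition to 2 standard errors. Each value that follows was picked out because the knockout effect differed between the tissues by the interaction test, or because a signal lay in probe sets outside the comparisons of genes.

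Armh4 differed between the tissues by -0.997, Pla2g4e by -1.06 and Sv2c by -0.94 on the log2 scale. Over 21 alternatives the adjusted p of Armh4 ran from 0.000928 to 0.113 and passed in 16, and that of Pla2g4e ran from 0.0013 to 0.0908 and passed in 16. Sv2c ran from 0.00237 to 0.209 and passed in 9. The median difference between tissues was 0.31 for the myelin list, 0.31 for the ependymal and cilia list, 0.21 for the immediate early list and 0.23 for the oligodendrocyte precursor list. With an estimated correlation none of these lists passed (adjusted p = 0.853, 0.371, 0.926 and 0.371).

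Probe sets without a single gene symbol also passed the threshold. In knockout hippocampus 79 of 13767 passed, 21 higher and 58 lower, of which 60 carried several symbols and 19 were not listed. In knockout olfactory bulb 59 passed, 54 higher and 5 lower, of which 32 carried several symbols and 27 were not listed. The largest differences among them were 3.63 in hippocampus and 2.79 in olfactory bulb in absolute log2 value.

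The immediate early genes lay lower in knockout olfactory bulb, and the weighing concerns why. Time of day of collection is argued against only as far as it would move the 5 clock genes set for the test by over 0.5 log2. Per3 had the largest change of -0.21 (SE 0.074, limma adjusted p = 0.333), and with Dbp, Nr1d1, Per2 and Ciart lay within 0.5 of 0 at 2 standard errors. Of the wider clock list Bhlhe41 differed by 0.27 (SE 0.133, limma adjusted p = 0.475), and Per3 was lower in hippocampus too, as given below. A difference in collection time that moves these genes by less is not excluded. A state of the whole animal may have lowered the list in both tissues, where the mean change was -0.39 in olfactory bulb (exact permutation p = 0.1, the smallest that 3 against 3 can give) and -0.14 in hippocampus (exact permutation p = 0.4); the difference of 0.25 exceeded 2 standard errors under either pairing of the tissues, but its exact permutation p was 0.2 by animal code (SE 0.102) and 0.1, the smallest possible, by title number (SE 0.090), so the verdict turns on a pairing that the labels leave unsettled, and this stays open. A single library also stays open, since the median of -0.34 became -0.19 without wild-type replicate 3 and lay between -0.47 and -0.29 without each of the others. The genotype, the difference that the design names, stays among the open explanations as an untested hypothesis.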

How the results depend on the processing

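No alternative was added after the data were seen. Of the alternative values for the counts of genes and lists and the odds ratios, 89 stayed on their side of the threshold or lay within 1.5 times the count. Of the rest, 20 were weaker, 7 stronger and 1 reversed. For single genes named in the text and single lists, 2422 values stayed on their side of the threshold, 221 no longer passed, 1 newly passed and none reversed. The 2422 include genes called between the regions, which passed under every alternative, and values that never passed. They therefore do not measure how stable the calls between genotypes are. Mid1 kept its call in all 13 alternatives in each tissue, while Nr4a2 in olfactory bulb lost it in 9 of 13. The difference between tissues of Sv2c lost it in 12 of 21. Direction was compared only where a value passed in the main or the alternative setting, so a change of sign among values that never passed is not counted. Arrays with probe signal near background limit the smallest changes that can be seen.

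Fitting only the groups compared gave 28 genes in knockout hippocampus, 26 of them among the 51, and 36 in olfactory bulb, all among the 82; fewer arrays then estimate the spread. Every probe set gave 125 in hippocampus, 46 with a single gene symbol and 79 without, and 0 for the difference between tissues. Array weights gave 336, with all 51 among them, and 12. Trend and robust settings gave 136 in olfactory bulb and 181 for the animals' means. The animal as a fixed block gave 0 for the difference between tissues by code and 0 by title number, and as a random block by code 3, the same genes. An estimated correlation left 0 lists in hippocampus and 0 in olfactory bulb. The odds ratio of genes near Rasgrf2 was 0.984 within 20 Mb in hippocampus and 2.64 within 5 Mb, and in olfactory bulb 1.13 within 20 Mb and 1.42 within 40 Mb. Probe sets without a single gene symbol account for the higher hippocampal count over every probe set. For the others, apart from the fewer arrays, the cause was not tested.

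Leaving out 1 replicate at a time gave 30 to 43 genes in hippocampus, 35 to 105 in olfactory bulb, 0 to 4 for the difference between tissues, 69 to 134 for the animals' means, 6813 to 7714 between tissues in wild type and 6665 to 7625 in knockout. The lists ranged from 4 to 9 in hippocampus and from 1 to 5 in olfactory bulb. Fewer arrays lower the number of calls, and for counts that grew the cause was not tested.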

Other observations

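The tests of neighbouring genes, of the remaining Rasgrf2 signal, of list levels shared by an animal and of lists over other splits were chosen only after the result was seen; those of genes near Rasgrf2 and of gene counts over other splits were planned. The test of single mislabelled arrays replaced a void version run on 3 genes picked for their difference.

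In other groups single members passed, most of them only when adjusted over their list alone. In hippocampus 3 of 13 choroid plexus genes passed adjusted over the list alone, Calml4 (0.35), Clic6 (0.50) and the claudin gene Cldn2 (0.48), with 9 of 13 above 0 and a camera adjusted p of 0.297. Of 15 interferon and MHC genes B2m passed over all genes in hippocampus, though in 7 of 13 alternatives, and, at -0.40, over the list alone in olfactory bulb. The clock gene Per3 (-0.31) passed over its list alone in hippocampus. In olfactory bulb Tyms (0.33), a gene of DNA synthesis, and Eomes (0.36) passed over the progenitor cell cycle list alone. Gng13 (0.33), a G protein subunit gene of olfactory neurons, passed over its list alone, with a camera adjusted p of 0.805 for the 9 genes.

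Between the regions, GABAergic interneuron genes lay higher in olfactory bulb, with 10 of 14 past the threshold in that direction in each genotype and medians of -1.07 in wild type and -1.03 in knockout (camera adjusted p = 0.00409 and 0.00123, adjusted p = 0.11 and 0.0856 with an estimated correlation). The other 4 interneuron genes passed in the opposite direction in each genotype. Olfactory ensheathing glia genes also lay higher in bulb, 7 of 8 in each genotype, with 1 passing the other way (camera adjusted p = 0.00478 and 0.00198, adjusted p = 0.11 and 0.0856 with an estimated correlation). Of 13 myelin genes 10 were higher in hippocampus than in bulb in knockout (camera adjusted p = 0.00408, adjusted p = 0.622 with an estimated correlation), as were 7 of 10 ependymal and cilia genes (adjusted p = 0.0137, adjusted p = 0.221 with an estimated correlation). In wild type 4 of 13 myelin genes were higher and 2 lower in hippocampus (camera adjusted p = 0.272), and 2 of 10 ependymal and cilia genes were higher (adjusted p = 0.275).

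Genes past the threshold lay next to each other along the chromosomes, among them most of the genes that passed in both tissues. Of 108 such genes placed in assembly GRCm38.p6, Rasgrf2 left out, 42 had another within 10 neighbouring tested genes, where 10000 random draws had a median of 10 and a highest value of 30 (permutation p = 0.0001, the smallest they can give), in 16 runs such as Greb1l, Esco1, Abhd3, Riok3 and Cabyr, or Pts, Sdhd, Cryab and Layn. Differences confined to the segment around Rasgrf2 are argued against as the source of the runs, since 0% of the clustered genes lie on its chromosome (also 0 of 42 with Rasgrf2 kept among 109). Within 20 Mb of Rasgrf2 the odds ratio was 0.984 in hippocampus (Fisher's exact p = 1) and 1.13 in olfactory bulb (Fisher's exact p = 0.557), though 2.64 within 5 Mb in hippocampus (Fisher's exact p = 0.00981, adjusted 0.0666 over the 8 windows), 2.02 within 5 Mb in olfactory bulb (Fisher's exact p = 0.0645) and 1.42 within 40 Mb in olfactory bulb (Fisher's exact p = 0.0166, adjusted 0.0666). A single called gene farther than 10 tested genes from Rasgrf2 does not register in the runs. In hippocampus 1 of 49 genes within 5 Mb passed over all genes, and 3 within 40 Mb. These 3 were Sv2c, Ddx4 and Gzmk, the last named outside the rule. Ddx4 also passed in olfactory bulb, where 0 genes within 20 Mb did, so the 1 within 5 Mb was Sv2c or Gzmk. Differences at single genes near Rasgrf2 are therefore not excluded. Segments of another strain carried by one colony may account for the runs, as 40 of the 42 had the same sign in both tissues against 54 of 66 isolated genes (Fisher's exact p = 0.0747), and a strain variant under a probe would look the same and was not examined. Neighbouring genes regulated together after loss of RasGRF2 also stay open, as 19 of 26 neighbouring pairs shared their direction, where sign shuffles had a median of 13 and a 95th percentile of 17.

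Rasgrf2 signal remained in the knockout arrays, at the 74.2th percentile of genes in hippocampus and the 85.4th in olfactory bulb. A wrong genotype for a single array is argued against, since 0 of 12 arrays lay on the other genotype's side of a score of the genes called in the other tissue. Those genes were called in the same 6 animals, so Rasgrf2 itself bears on the labels of whole animals. Its change of -0.58 in hippocampus (limma adjusted p = 0.00197) argues against an exchange of the genotypes as a whole. For a wrong label of an animal, 0 of 6 hippocampal arrays lay on the other side of its midpoint. This restates the separation of the Rasgrf2 values already seen and is not a separate test. Probes outside the deleted part of the gene may account for the signal, and no biological explanation was tested.

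Levels of the immediate early list in the tissues of an animal, centred on the genotype, correlated over 6 animals with r = 0.737 under the animal code (one-sided exact permutation p = 0.111, rho = 0.486 with exact permutation p = 0.306) and r = 0.797 under the title number (one-sided exact permutation p = 0.0833, rho = 0.829 with exact permutation p = 0.0833). Without the 2 animals farthest from the median r was 0.56 and 0.606. Neither of the 2 relations passed.

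With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split gave 51 genes in hippocampus (highest other 0, 1 split with as many), 82 in olfactory bulb (0, 1 split), 3 for the difference between tissues (1, 1 split), 115 for the animals' means (0, 1 split), 8148 between tissues in wild type (3, 1 split) and 7804 in knockout (0, 1 split). For lists it gave 6 in hippocampus, where 5 of the 10 splits gave as many and the highest other gave 8, and 3 in olfactory bulb, where 3 splits gave as many and the highest other gave 4.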
